A study of Danio rerio with 5 samples.

How the data were processed

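Small RNAs were sequenced from whole embryos of the AB* wild-type strain of zebrafish at 4 developmental stages, named 256-cell, sphere, shield and 1dpf (1 day post fertilization) in the labels. Per the labels' protocols, total RNA was isolated with Trizol, RNAs of 15 to 30 nt were cut from a denaturing gel, linkers were added, and the cDNA made by RT/PCR was sequenced on an Illumina instrument. The labels list 5 samples. The file of 1 library per stage was analysed, and sphere replicate 2 was not analysed here. No molecular identifiers are mentioned in the labels, so reads copied by PCR could not be told from separate molecules.

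Each deposited file lists distinct sequences with a read count, and the authors normalised none of these counts: the abundance column, per the file headers, holds whole numbers that sum to a different total in each file. Beside each sequence stand 1 matched repetitive element and its type, per the file headers. The submitters' processing notes name Bowtie, with no version. The genome build, the repeat annotation, the mismatches allowed and the filters are not given in the sources used here. Every listed sequence carries an element, so the files hold the repeat-matched part of each library. The total of a file is therefore not the depth of its library, and the amount of repeat-matched RNA per stage cannot be compared. All levels are shares of the listed reads or reads per 1000000 listed reads (RPM) within a library. In the 256-cell file a further deposited column of another kind, the size, equalled the number of letters of the sequence in all 125873 rows and was not used otherwise. No sequence was listed more than 1 time in a file.

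The files give an element but no position and no strand, and no genome was used. The results planned on genome windows, chromosomes, soft-masked sequence and the strand of genes were not made, and the gene lists were not used, because the files name repeats and not genes. The rule fixed for naming genes was applied to repetitive elements instead, a choice made after the files were seen. It named the 10 elements with the highest mean RPM over the 4 libraries. Of the elements with at least 100 reads over the 4 libraries, it named the 6 with the largest and the 6 with the smallest log2 ratio of 1dpf to 256-cell, with a pseudocount of 1 RPM. It also named the 3 most abundant sequences of each library. Low complexity sequences, listed in 2 of the 4 files, were kept in the totals and left out of the ranking. Other elements named in the text were chosen after their values were seen. Families were taken from the start of the element names as the files give them. A sequence that matches several elements is listed under 1 of them. Of the sequences shared by a pair of files, 95.9% to 96.2% were listed under the same element and 99.5% to 99.6% under the same type, so values of types are firmer than those of single elements. The same share by family was not measured.

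The share of reads with U at the 5′ end, the share with A at position 10 and the mean length were weighted by read count over all listed lengths. Sequences are listed in DNA letters, and T is written as U where base shares are given. For the ping-pong overlap, the share of pairs at 10 nt was taken among pairs of different sequences whose first 8, 9, 10, 11 or 12 nt were reverse complements, weighted by the product of their read counts. Longer overlaps compare more bases and match less often by chance. A comparison of the same 10 bases at every overlap from 10 to 18 nt was therefore added after the data were seen: positions 1 to 10 of a sequence were set against the 10 bases of another that end at the overlap length. Palindromic 10-mers were left out of it. Numbers of distinct sequences and the sharing of sequences between stages were computed after each library was thinned to 166714 reads, the total of the smallest, in 20 random draws.

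With 1 library per stage there is no replicate error, no test between stages was made, and no p-value is given. Shares have exact (Clopper-Pearson) 95% binomial intervals, differences of shares have Newcombe intervals, and ratios of RPM have exact conditional binomial intervals. The mean length difference has a large-sample 95% interval. Ping-pong shares have the SD of 20 Poisson resamplings of the read counts. All of these cover counting error only. A single read made up 0.0006% of the 256-cell reads and 0.000094% of the shield reads. A count of 0 allows up to 3 reads, which is 18.0 RPM at 256-cell, 4.81 RPM at sphere, 2.81 RPM at shield and 7.86 RPM at 1dpf. For families with at least 5 elements of 100 reads, the median log2 ratio was placed among those of 10000 random lists of elements matched on mean RPM in 10 bins, which describes these libraries only.

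The alternatives fixed before the data were examined were counting each distinct sequence 1 time, keeping 24 to 30 nt reads, keeping sequences with at least 2 reads, leaving out the 10 most abundant sequences, overlaps of 5 to 15 nt, thinning or full depth, equality over the first 20 nt, and a pseudocount of 5 RPM. Results on repeat types, on shield against 256-cell and on reads of 20 to 23 nt, with their alternatives, were added after the data were seen. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data. In 20 settings of the pair counting, 0 differed from a direct count. In a simulated comparison of 1dpf with 256-cell over 869 elements, the interval held the true ratio for 96% of 100 elements made 4-fold higher, for 93% of 100 made 4-fold lower and for 95.1% of the 669 left unchanged. The simulated counts were Poisson draws, so this checks the code and not PCR copies or the spread between libraries.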

Results

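The study profiled small RNAs in early zebrafish embryos, and the 4 files analysed hold the reads that match repetitive elements, a known source of piRNAs. These are small RNAs bound by Piwi proteins that silence transposons, mostly in germ cells. The stages run, in order of development, from 256-cell through sphere and shield to 1dpf. The listed reads numbered 166714 at 256-cell, 623796 at sphere, 1068353 at shield and 381500 at 1dpf. They fell on 125873, 398892, 674777 and 268209 distinct sequences, of which 87.5%, 83.4%, 83.1% and 86.3% were seen in a single read. Each stage was represented by 1 library, so no difference between stages was checked against replicates, and all intervals are 95% intervals of counting error only.

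The deposited design asks which small RNAs are present at each stage, and the size of the reads was compared first. Lengths ran from 18 to 32 nt with a peak at 26 nt at 256-cell and sphere and at 27 nt at shield and 1dpf. Reads of 24 to 30 nt made up 79.8% at 256-cell (exact 95% interval 79.7 to 80.04), 77.5% at sphere (77.4 to 77.6), 84.1% at shield (84.0 to 84.2) and 73.3% at 1dpf (73.2 to 73.4). The 1dpf library held the largest share of shorter reads, with 20.5% of its reads at 20 to 23 nt against 15.2% at 256-cell, 19.3% at sphere and 12.7% at shield. Mean length was 25.1, 25.3, 25.7 and 25.0 nt in stage order. The 1dpf mean lay below the 256-cell mean by 0.124 nt (interval of the difference -0.139 to -0.109). The sign turned among 24 to 30 nt reads, where the 1dpf mean was 26.4 nt and the 256-cell mean 26.1 nt, and when each distinct sequence was counted 1 time.

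**Figure D1:**
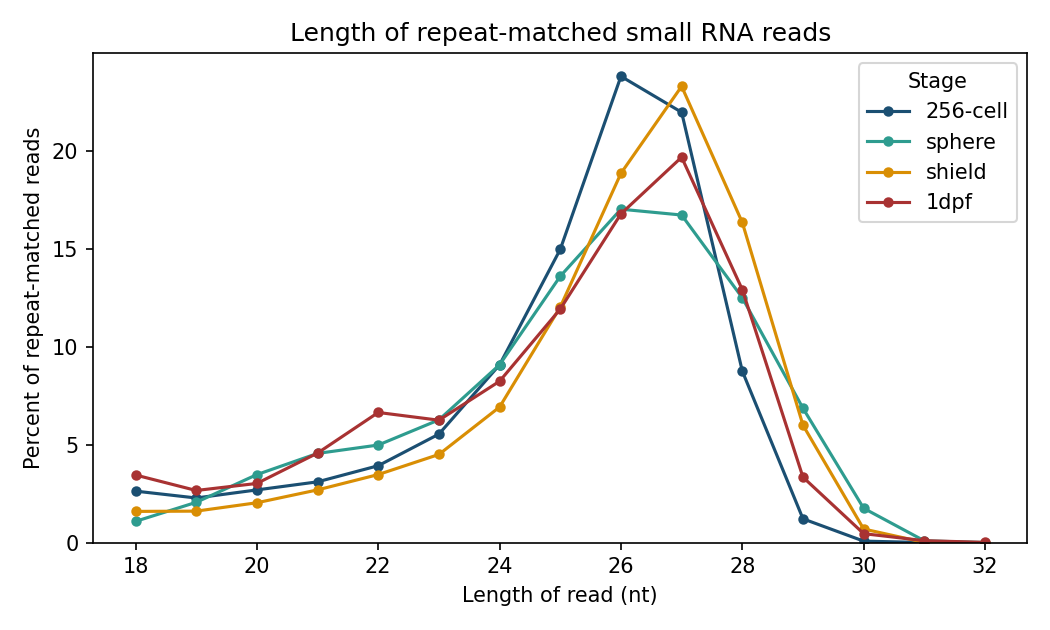
Length in nt (x axis) against the percent of repeat-matched reads (y axis), with a line for each of the 4 stage libraries. All 4 lines peak at 26 or 27 nt, and the 1dpf line has a shoulder at 22 nt, with 6.64% of its reads.

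The reads were next compared for the 2 base preferences of piRNAs, U at the 5′ end (primary piRNAs) and A at position 10 (secondary piRNAs made by the ping-pong cycle). The 5′ U share was 76.0% at 256-cell (75.8 to 76.2), 80.9% at sphere (80.8 to 81.0), 60.2% at shield (60.2 to 60.3) and 69.3% at 1dpf (69.1 to 69.4). From 256-cell to 1dpf it was 6.74 percentage points lower (interval -6.99 to -6.49), and 4.18 points lower among 24 to 30 nt reads. The shield library was 15.7 points below 256-cell (-16.0 to -15.5). The shield reads also differed at the neighbouring base: among 24 to 30 nt reads, A stood at position 2 in 41.1% at shield against 17.6% to 21.7% in the other libraries, and reads that began with UU made up 3.63% at shield against 15.1%, 21.7% and 14.6% at 256-cell, sphere and 1dpf.

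A at position 10 was found in 44.1% of reads at 256-cell (43.8 to 44.3), 39.4% at sphere (39.3 to 39.5), 51.1% at shield (51.0 to 51.2) and 44.5% at 1dpf (44.3 to 44.6). At positions 11 to 18 the mean share of A was 28.3%, 24.3%, 29.7% and 28.3% in the same order, so each library had an excess at position 10. The 1dpf share exceeded that of 256-cell by 0.430 points (0.144 to 0.716). The difference was 1.61 points among 24 to 30 nt reads and 0.282 points without the 10 most abundant sequences, where its interval included 0 (-0.0058 to 0.570). The shield share exceeded it by 7.05 points (6.79 to 7.30). In 24 to 30 nt reads that lacked 5′ U, A at position 10 reached 67.0% at 256-cell, 63.0% at sphere, 67.6% at shield and 65.5% at 1dpf, against 39.3%, 36.1%, 41.7% and 40.4% in reads with 5′ U. LTR, LINE and DNA transposon reads of 24 to 30 nt each showed this split in all 4 libraries. The far fewer SINE and satellite reads showed it in none. At 1dpf their share without 5′ U was 44.7% in SINEs and 46.1% in satellites, against 51.3% and 55.2% with 5′ U. The LINE reads without 5′ U had A at position 10 in 71.5% at 256-cell (69.9 to 73.1) and 70.4% at 1dpf (69.4 to 71.4).

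**Figure D2:**
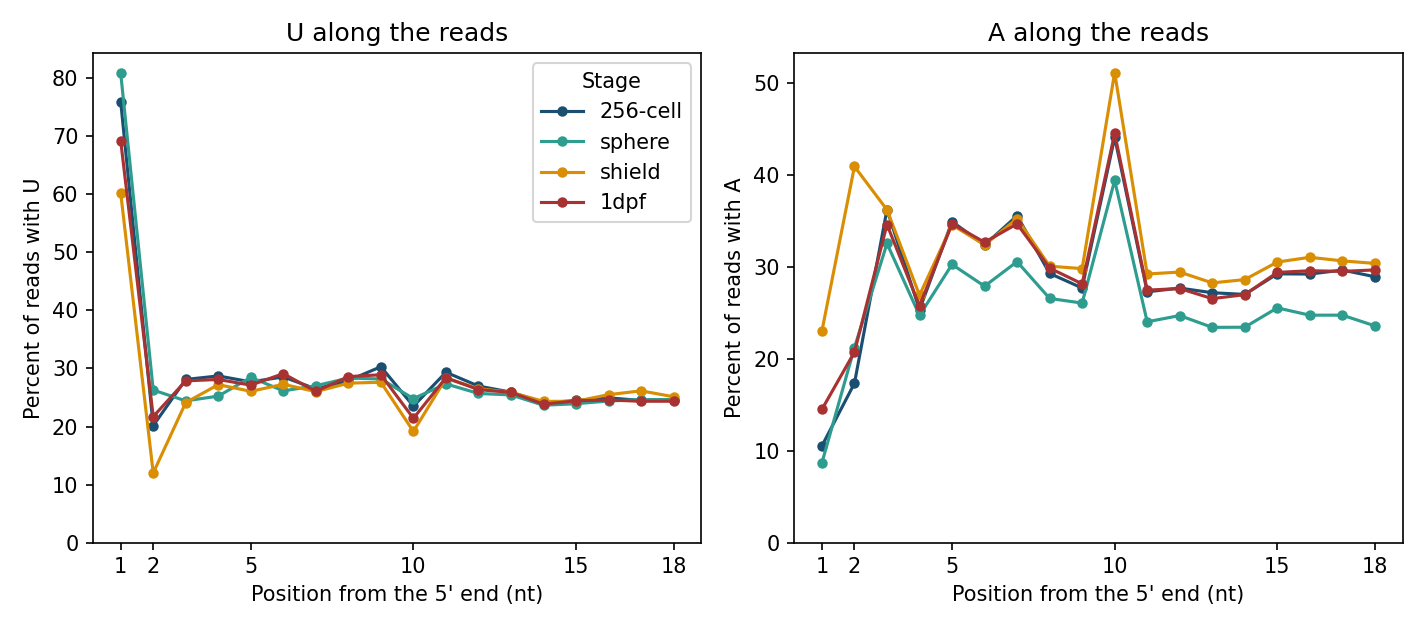
Position from the 5′ end in nt (x axes) against the percent of reads with U (left) or A (right), with a line for each of the 4 stage libraries. U peaks at position 1 at 60.2% to 80.9%, A peaks at position 10 at 39.4% to 51.1%, and the shield line stands apart at positions 1 and 2.

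Ping-pong partners are cut so that their first 10 nt are complementary. When the same 10 bases were compared at each overlap, 29.8% of complementary pairs overlapped by 10 nt at 256-cell (SD of counting error 0.457 points), 36.4% at sphere (0.349), 33.3% at shield (0.137) and 26.8% at 1dpf (0.369). The count at 10 nt was 3.40, 4.59, 3.99 and 2.92 times the mean of the overlaps of 11 to 18 nt. Among pairs listed under the same element with each sequence counted 1 time, the share at 10 nt was 54.7%, 54.2%, 47.6% and 39.1% in stage order. At 1dpf, pairs of 15 to 18 nt overlap were more frequent than at 11 to 14 nt, reaching 11.2% at 18 nt, against 8.05% at 256-cell.

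The planned measure gave another order. Among overlaps of 8 to 12 nt over all reads, the share at 10 nt was 15.9% at 256-cell, 21.8% at sphere, 19.4% at shield and 24.2% at 1dpf, a difference of 8.34 points between 1dpf and 256-cell (7.17 to 9.51). The resamplings behind this interval gave SDs of 0.317 points at 256-cell and 0.508 at 1dpf. Another set of resamplings gave 0.518 and 0.595, so the interval may be too narrow. At 1dpf, 38.3% of the pairs at 10 nt came from sequences that begin with the palindrome TGTGATCACA, most of them listed under the DNA transposon DNA-2-32_DR. Without palindromic 5′ ends the difference was 0.599 points. It turned to -1.04 points when each distinct sequence was counted 1 time, and to -3.04 points when the same 10 bases were compared. The last share is taken over overlaps of 10 to 18 nt. It cannot tell fewer 1dpf pairs at 10 nt from more 1dpf pairs at 15 to 18 nt.

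**Figure D3:**
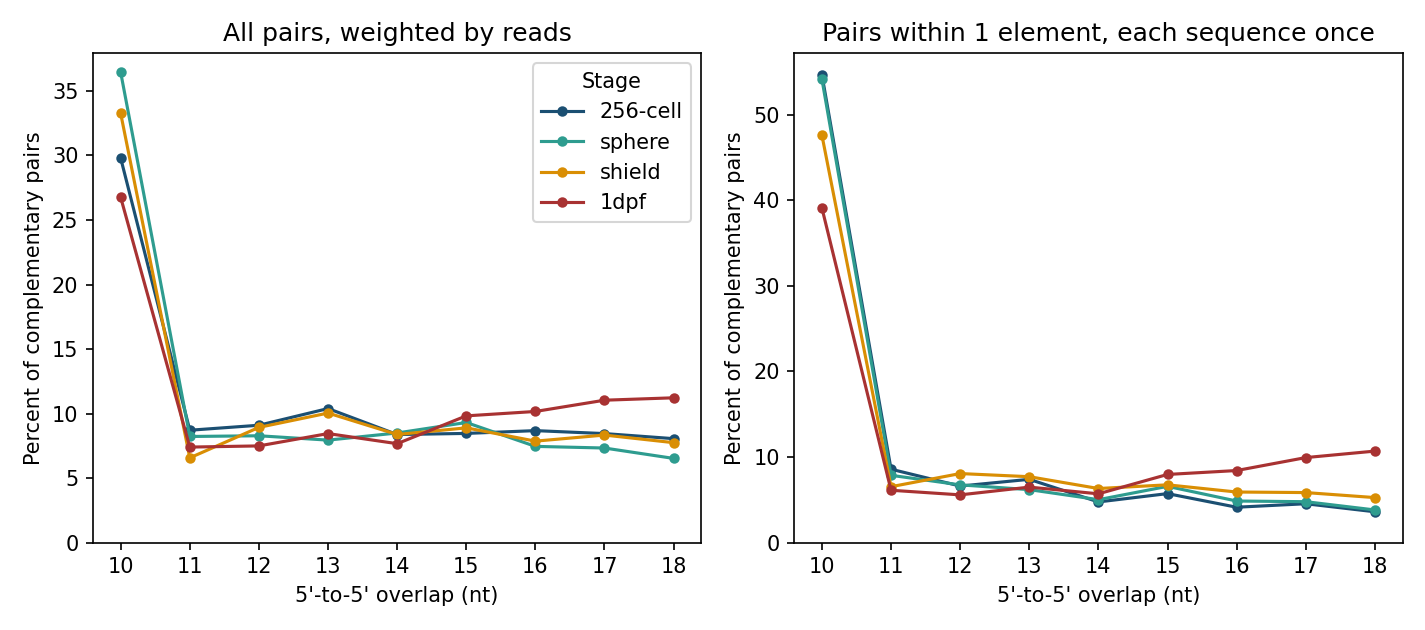
5′-to-5′ overlap in nt (x axes) against the percent of complementary pairs at overlaps of 10 to 18 nt (y axes), for all pairs weighted by reads (left) and for pairs within 1 element with each sequence counted 1 time (right), with a line for each of the 4 stage libraries. The highest point is at 10 nt in all 4 libraries, and the 1dpf line climbs again towards 18 nt.

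LTR elements supplied most reads at all 4 stages. LTR retrotransposons took 63.9% of reads at 256-cell (63.7 to 64.1), 67.1% at sphere (67.0 to 67.3), 62.7% at shield (62.6 to 62.8) and 58.7% at 1dpf (58.6 to 58.9). DNA transposons took 22.2% (21.97 to 22.4), 19.03% (18.9 to 19.1), 24.001% (23.9 to 24.1) and 28.2% (28.1 to 28.3) in the same order. LINEs took 10.7%, 9.96%, 11.8% and 11.01%, SINEs 0.852%, 0.544%, 0.507% and 0.813%, and satellites 1.64%, 2.54%, 0.867% and 1.01%. From 256-cell to 1dpf the LTR share was 5.19 points lower (-5.46 to -4.91) and the DNA transposon share 6.04 points higher (5.79 to 6.28). Among 24 to 30 nt reads these differences were smaller, -2.76 and 1.89 points.

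The DNA transposon difference lay mostly in reads of 20 to 23 nt. DNA transposon reads of that size made up 8.86% of all reads at 1dpf and 3.31% at 256-cell. Within the size class, DNA transposons took 43.3% of reads at 1dpf (42.9 to 43.6), against 21.7% at 256-cell (21.2 to 22.2), 19.5% at sphere (19.3 to 19.8) and 25.0% at shield (24.8 to 25.2). The 1dpf share exceeded the 256-cell share by 21.6 points (20.99 to 22.2). The difference was 10.8 points with each distinct sequence counted 1 time, 42.6 points for sequences with at least 2 reads and 16.6 points without the element ANGEL. LTR elements took 44.5% of this size class at 1dpf and 59.2% at 256-cell.

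The elements ranked much alike in the 4 libraries. The files named 980 elements, 942 of them in all 4 libraries. Over the 863 elements with at least 100 reads, Spearman's rho of log2 RPM ran from 0.933 (256-cell against 1dpf) to 0.956 (sphere against shield). These are correlations across elements, which are not independent replicates. Of the 863, 755 (87.5%) lay within 2-fold between 256-cell and 1dpf, 73 were more than 2-fold higher at 1dpf and 35 more than 2-fold lower. The median log2 ratio was 0.06.

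The 10 elements with the highest mean held 14.01% of reads at 256-cell, 16.7% at sphere, 14.5% at shield and 13.3% at 1dpf, and 8 of them were LTR elements. Gypsy101-I_DR-int, the internal part of a Gypsy retrotransposon, led at 256-cell with 29818 RPM and had 22988 RPM at 1dpf, a ratio of 0.771 (0.745 to 0.798). LTR1_DR had 22488 RPM at 256-cell and 22351 RPM at 1dpf, a ratio of 0.994 (0.956 to 1.03), so no difference was detectable between them. In LTR1_DR 52.0% of reads had 5′ U at 256-cell and 31.7% at shield, the lowest among these 10. BHIKHARI-5-I_DR-int, from a zebrafish LTR retrotransposon, was highest at sphere, with 29103 RPM against 16921 RPM at 256-cell (1.72-fold, 1.65 to 1.79). The 4 DIRS elements among the 10, retrotransposons that use a tyrosine recombinase, were also higher at sphere, though some other DIRS elements were lower: DIRS1_DR was 1.87-fold (1.76 to 1.98), DIRS1a_DR 1.92-fold (1.81 to 2.05), DIRS-2_DR 1.61-fold (1.53 to 1.69) and DIRS-N1_DR 1.07-fold (1.01 to 1.13) their 256-cell RPM. At 1dpf DIRS1_DR was at 0.993 times its 256-cell RPM (0.931 to 1.06). GypsyDR2 had 11319 RPM at 256-cell and 9594 RPM at 1dpf. The DNA transposons among the 10 were Kolobok-1_DR, with a ratio of 1dpf to 256-cell of 0.733 (0.695 to 0.773), and Polinton-1_DR, with 1.05 (0.995 to 1.12).

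By family, Gypsy took 33.3% of reads at 256-cell, 33.6% at sphere, 30.6% at shield and 29.4% at 1dpf, and DIRS 11.1%, 14.04%, 10.99% and 10.3%. Of 274 Gypsy elements with at least 100 reads, 165 were lower and 109 higher at 1dpf than at 256-cell. Their median log2 ratio of -0.15 lay below those of all 10000 random lists of the same size and mean level. Of 63 BEL elements 39 were lower, with a median of -0.15 at percentile 0.175. Of 78 hAT elements 56 were higher, with a median of 0.32 at percentile 99.0, and of 25 TDR elements 23 were higher, with a median of 0.57 at percentile 99.97. The random lists treated elements as independent and were drawn for reads of all lengths only. Among 24 to 30 nt reads the medians kept their sign and were smaller in size for these 4 families: -0.07 for Gypsy, -0.03 for BEL, 0.23 for hAT and 0.25 for TDR, where the median of all 863 elements was 0.07. ERV, Copia and DIRS elements had medians of -0.06, -0.12 and -0.10 over all reads and of 0.04, 0.06 and -0.01 among 24 to 30 nt reads.

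**Figure D4:**
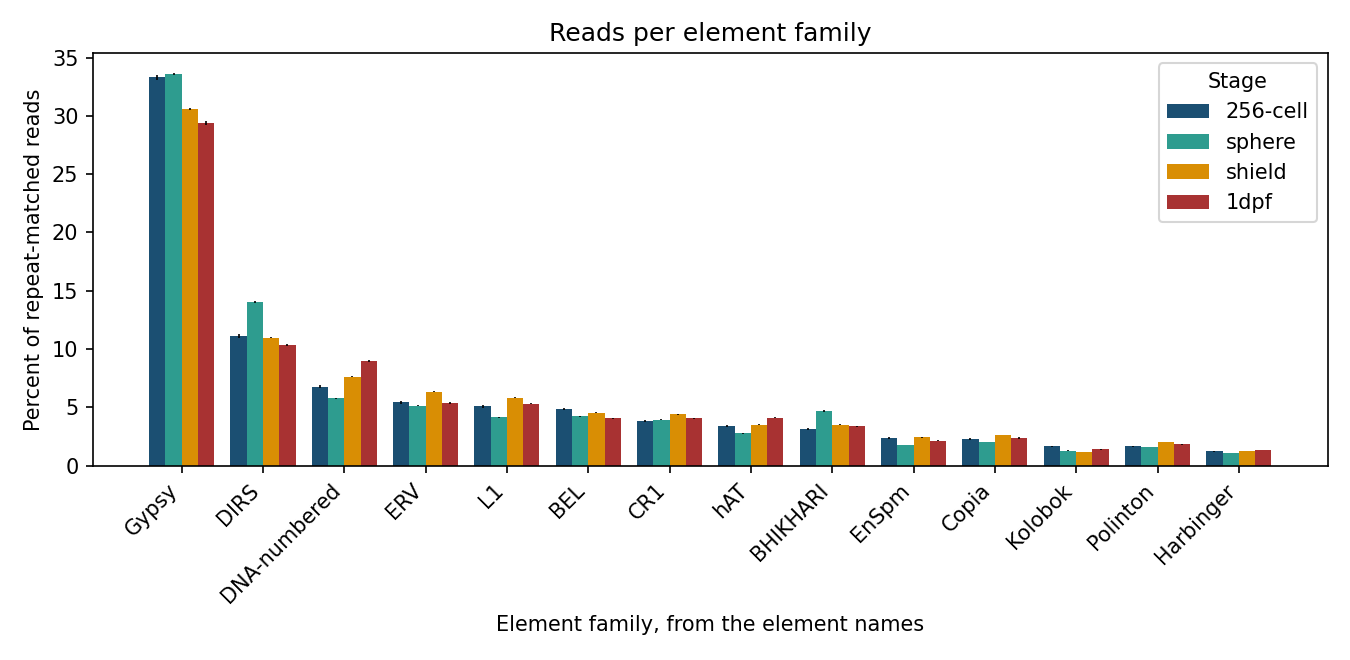
Element families taken from the element names (x axis) against the percent of repeat-matched reads (y axis), with a bar for each of the 4 stage libraries and exact 95% binomial intervals of counting error as error bars. Gypsy holds 29.4% to 33.6%, DIRS is highest at sphere with 14.04%, and elements named DNA with a number are highest at 1dpf with 9.02%.

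The 6 elements with the largest ratio of 1dpf to 256-cell were hAT-N60_DR, HATN4_DR, Gypsy61-I_DR-int, DNA-2-32_DR, Gypsy-24-I_DR-int and DNA-8-11_DR. Gypsy61-I_DR-int had 7 reads at 256-cell and 147 at 1dpf (9.18-fold, 4.34 to 23.2), spread over 132 sequences, and was 3.44-fold higher at sphere (1.60 to 8.79) and 6.96-fold at shield (3.34 to 17.4). The other 5 rested largely on short reads. HATN4_DR was 9.91-fold higher (5.58 to 19.4) with 87.1% of its 1dpf reads at 20 to 23 nt. DNA-8-11_DR was 7.35-fold higher (5.99 to 9.10) with 82.5% of reads in that class. DNA-2-32_DR was 7.82-fold higher (6.38 to 9.69), and 960 of its 1754 reads at 1dpf were the 21-nt sequence TGTGATCACATGGGAAAACGT. Gypsy-24-I_DR-int was 7.56-fold higher (6.35 to 9.05), and 1805 of its 2334 reads were the 18-nt sequence GTCCCTGTTCGGGCGCCA, which the other files list under other Gypsy elements. Among 24 to 30 nt reads the log2 ratios were 0.27 for DNA-2-32_DR, 0.11 for Gypsy-24-I_DR-int, 0.61 for HATN4_DR, 1.25 for DNA-8-11_DR, 1.96 for hAT-N60_DR and 3.48 for Gypsy61-I_DR-int. hAT-N60_DR had 2 reads at 256-cell and 70 at 1dpf (15.3-fold, 4.08 to 129), and 37 of the 70 were a single sequence.

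The 6 elements with the smallest ratio were Gypsy147-I_DR-int, Gypsy9-LTR_DR, Copia-9-LTR_DR, Gypsy54-I_DR-int, Gypsy-18-I_DR-int and Polinton-2N1_DR. Gypsy147-I_DR-int was the most abundant of them, with 3911 RPM at 256-cell, 747.04 RPM at sphere, 337 RPM at shield and 566 RPM at 1dpf, 6.91-fold lower at 1dpf than at 256-cell (5.91 to 8.09). Its 1dpf reads showed 65.7% 5′ U and 51.9% A at position 10. Gypsy-18-I_DR-int had 318 RPM at 256-cell, 9.62 RPM at sphere, 88.9 RPM at shield and 73.4 RPM at 1dpf, and Gypsy54-I_DR-int was at 329.9 RPM at 256-cell, 141 RPM at sphere, 329 RPM at shield and 65.5 RPM at 1dpf. Gypsy9-LTR_DR, with 68 reads at 256-cell and 24 at 1dpf, was 6.48-fold lower at 1dpf (4.02 to 10.8) over all reads. Its log2 ratio among 24 to 30 nt reads was 0.0068. Copia-9-LTR_DR was 5.10-fold (2.57 to 10.7) and Polinton-2N1_DR 3.39-fold (1.98 to 5.87) lower. They had few reads: 29 at 256-cell and 13 at 1dpf for Copia-9-LTR_DR, and 37 and 25 for Polinton-2N1_DR. The elements with the smallest and the largest ratios were picked by that ratio, and their intervals take no account of this.

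The most abundant sequences were mostly shorter than piRNAs. The same 3 sequences led at 256-cell and sphere. All were listed under the satellite MOSAT-2_DR and overlapped each other. The first, GTACGCAGTTGGCTGGCTTT, had 2513 RPM at 256-cell, 4806 RPM at sphere, 60.8 RPM at shield and 396 RPM at 1dpf. MOSAT-2_DR as a whole had 11163, 19562, 1441 and 3641 RPM in stage order, with 85.0%, 87.2%, 35.8% and 58.2% of its reads at 20 to 23 nt. At shield the leading sequence had the size of a piRNA, 27 nt, was listed under EnSpm-N3_DR and had 957 RPM, against 228 RPM at 256-cell, 68.9 RPM at sphere and 401 RPM at 1dpf. The second and the third at shield were 18-nt sequences under Gypsy elements that end in CCA. At 1dpf the leading sequences were the 18-nt and 21-nt sequences named above and a 19-nt sequence of DNA-8-13_DR with 1481 RPM.

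Few sequences recurred in all 4 libraries. Most sequences were seen in a single read, and no repeat library of a stage was compared. Low sharing therefore does not show that sequences belong to a stage. At an equal depth of 166714 reads, the libraries held 125873 distinct sequences at 256-cell, 128217 ± 209 at sphere, 135059 ± 115 at shield and 129610 ± 142 at 1dpf (SD over 20 draws). The 1dpf number was 1.03 times that of 256-cell. For sequences with at least 2 reads after thinning the ratio turned to 0.880. At that depth, 12.5% of reads at 256-cell, 11.7% at sphere, 9.64% at shield and 11.6% at 1dpf had a sequence found in all 4 libraries, and 62.4%, 64.8%, 69.0% and 63.4% had a sequence found in no other. The share found in all 4 was 0.884 points lower at 1dpf than at 256-cell, 5.05 points lower at full depth and 0.0924 points lower with each distinct sequence counted 1 time. At full depth 13142 of 1251373 sequences occurred in all 4 libraries. Reads of these shared sequences had 5′ U in 86.8% at 256-cell, 86.3% at sphere, 81.1% at shield and 80.5% at 1dpf, and A at position 10 in 39.7%, 33.4%, 45.5% and 39.3%.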

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

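Low complexity sequences were singled out because they appear in the files of 2 stages only and have no comparison of their own, though the totals include them. They made up 0.560% of reads at 256-cell (933 reads) and 0.588% at sphere (3669 reads). The shield and 1dpf files list 0 such reads, and 3 of these sequences occur in each of those files under another type. The type label of 1 element did differ between the files. It was satellite with a question mark for its 9 reads at 256-cell and for 8 of its 50 at shield. Its 12 reads at sphere and 42 at 1dpf had no question mark. Whether the repeat annotation or a filter differed more widely between the files is not documented, and such a difference would bear on every share compared between them.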

How the results depend on the processing

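Differences are in percentage points and, unless stated, 1dpf minus 256-cell. No paired analysis was possible because each stage had 1 library, and leaving out replicates was not possible for the same reason. The alternatives for shield, LTR and DNA transposons, the 3 last ones for ping-pong and those named for elements except the pseudocount were chosen after the data were seen. Settings that need positions (uniquely placed sequences, other windows, exons) were not run.

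The 5′ U difference (-6.74) kept its sign at -4.18 for 24 to 30 nt, -8.38 for at least 2 reads, -6.30 without the 10 most abundant sequences and -6.50 with each sequence counted 1 time. The A share at position 10 (0.430) was 1.61, 1.03, 0.282 and 0.716 in that order, and the interval of the third value included 0 (-0.0058 to 0.570). For shield minus 256-cell, 5′ U (-15.7) was -16.9, -14.5, -15.97 and -19.3, and A at position 10 (7.05) was 6.45, 10.97, 6.67 and 5.78. The LTR share (-5.19) was -2.76, -6.60, -5.77 and -4.83, and -5.55 without low complexity sequences. The DNA transposon share (6.04) was 1.89, 9.48, 5.74 and 4.27. Its share of 20 to 23 nt reads (21.6) was 42.6 for at least 2 reads, 19.1 without the 10 most abundant, 10.8 with each sequence counted 1 time and 16.6 without ANGEL. The mean length difference (-0.124 nt) was reversed at 0.266 for 24 to 30 nt and 0.0197 with each sequence counted 1 time, and was -0.375 for at least 2 reads and -0.0714 without the 10 most abundant. The 24 to 30 nt setting leaves out the reads of 18 to 23 nt, 26.6% at 1dpf and 20.2% at 256-cell, and the few over 30 nt. For the other turn the cause was not tested.

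The ping-pong difference (8.34) stayed at 8.08 after thinning and was 0.263 for overlaps of 5 to 15 nt. It was reversed at -1.04 with each sequence counted 1 time. It was 0.599 without palindromic 5′ ends, and reversed at -3.04 with the same 10 bases and at -15.6 within elements. The -3.04 and -15.6 are differences of shares over overlaps of 10 to 18 nt. Pairs at 18 nt were more frequent at 1dpf: 11.2% against 8.05% at 256-cell, and 10.7% against 3.60% within elements. These shares therefore cannot tell fewer pairs at 10 nt from more pairs at 15 to 18 nt. Only the reads with palindromic 5′ ends were left out to reach 0.599; for the turns the cause was not tested. The ratio of distinct sequences (1.03) was 2.13 at full depth, where depth differs, and reversed at 0.880 for at least 2 reads, where the cause was not tested. The shared reads (-0.884) were -5.05 at full depth, -0.0924 with each sequence counted 1 time and -2.23 for the first 20 nt. Of the 22 named elements, all were within their counting intervals with a pseudocount of 5 RPM. With 24 to 30 nt reads 9 were, 12 moved and Gypsy9-LTR_DR turned, from -2.68 to 0.0068 on the log2 scale, where the cause was not tested. With each sequence counted 1 time 10 were and 12 moved. Elements whose main interval included 0 were not counted as turned; of these LTR1_DR and DIRS1_DR changed sign under both settings and DIRS1a_DR with each sequence counted 1 time. The 256-cell library, with 166714 reads, limits every comparison made with it.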

Other observations

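The tests of CCA ends at longer lengths, of overlaps within ANGEL and of the 5′ U share at shield were chosen after the results were seen.

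Short reads of DNA transposons set the 1dpf library apart. Among elements with at least 100 reads in a library, 26 of 615 had more than 50% of their reads at 20 to 23 nt at 1dpf, against 2 of 368 at 256-cell, 4 of 642 at sphere and 2 of 782 at shield. These sets of elements differ: over the 365 with 100 reads at both 256-cell and 1dpf the counts were 7 at 1dpf, 6 of them DNA transposons, and 2 at 256-cell. Of the 26, 25 were DNA transposons. They included hAT-N32_DR with 88.0% (85.4 to 90.3), TDR22 with 74.5% (72.5 to 76.4) and TDR19 with 71.2% (66.7 to 75.4). Over the same 365 elements the median share at 20 to 23 nt went from 13.7% to 18.9% in 95 DNA transposons, where it was higher at 1dpf in 82, and from 13.8% to 15.1% in 221 LTR elements, where it was higher in 145.

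ANGEL, a short inverted-repeat DNA element, had the most such reads at 1dpf, with 2915 RPM at 256-cell, 2046 at sphere, 2963 at shield and 21379 at 1dpf. Its reads were mostly 20 to 23 nt at every stage: 61.1% at 256-cell, 73.0% at sphere, 63.0% at shield and 90.6% at 1dpf. The peak was at 22 nt in each library, so this size class was present before 1dpf. Over-amplification of a few sequences is argued against, since the 10 most abundant held 15.8% of these reads and 2489 sequences were seen. A general loss of longer reads is argued against as the whole cause. It predicts fewer ANGEL reads of 24 to 30 nt at 1dpf, and these went from 672 RPM at 256-cell to 1402 RPM. Part of that rise was at 24 nt, near the 22-nt peak, with 120 and 498 RPM. At no length from 25 to 30 nt was the RPM lower at 1dpf. It went from 150 to 157 RPM at 26 nt and from 156 to 309 RPM at 27 nt. The share at 20 to 23 nt changed by 29.5 points in ANGEL, against a median of 2.28 points over the 365 elements. That contrast does not decide, because ANGEL was picked for its short reads. Perfectly paired 22-nt strands with 2-nt 3′ overhangs overlap by 20 nt. The criterion allowed 19, 20 or 21 nt as the most frequent overlap of 22-nt ANGEL sequences. Such strands are argued against at 1dpf, where it was 16 nt (24.8% of pairs, 6.86% at 20 nt). At shield 13 nt led (25.5%), outside the criterion, but that peak rests on 24 distinct pairs and does not decide. With each sequence counted 1 time, 16 nt led at 1dpf (15.3%) and at shield (15.6%). Sphere met the criterion with 19 nt (68.3%, 6.10% at 20 nt), which also led with each sequence counted 1 time (37.5%). It does not decide either, as that peak rests on 12 distinct pairs. At 256-cell 15, 17 and 18 nt tied with 4 pairs each, too few to decide. Pairing with mismatches was not tested and no miRNA sequences were used here, so miRNAs, a hairpin of the inverted repeat, or a stage difference in its processing, may still be the source and stay open, as does a difference in library preparation.

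Reads of 18 nt that end in CCA, the 3′ end of mature tRNAs, made up 6.27% of the 18-nt LTR reads at 256-cell, 20.4% at sphere, 27.4% at shield and 55.4% at 1dpf, against 0.701% to 2.22% in DNA transposons and 0.286% to 2.42% in LINEs; SINEs had 6.19% at 256-cell, where LTR elements did not stand apart from them, and 3.95% at 1dpf. LTR retrotransposons are primed by tRNAs whose 3′ ends are complementary to their primer-binding sites. A preference for CCA at every length is argued against, since 1.77% of LTR reads of 26 to 28 nt ended so at 1dpf. Of the 1dpf reads that began with 27 such 18-mers, 99.9% stopped at the CCA, against 35.8% for 31 LTR 18-mers without it. That is consistent with tRNA 3′ fragments listed under LTR elements through their primer-binding sites, which is a hypothesis, as no tRNA sequences were used here.

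The low 5′ U share at shield came with a shift at the next base. Of the 24 to 30 nt reads with 5′ U, 5.89% had U at position 2 at shield against 19.2% to 26.1% in the other libraries, and 37.2% had A against 11.8% to 18.6%. Such a pattern is what a bias in linker ligation of that library could give. More secondary piRNAs at shield cannot be told apart from it. The 5′ U share was lowest at shield within 3 of the 4 bases at position 2. The exception was A, with 55.7% at shield, 52.3% at 256-cell, 50.003% at 1dpf and 71.4% at sphere. A at position 10 in reads without 5′ U was highest at shield, at 67.6% (67.5 to 67.8). It was 67.04% at 256-cell (66.5 to 67.6). Their difference was given no interval of its own and does not decide. With 1 library per stage, stage and library preparation are confounded.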
